A study of Homo sapiens with 8 samples.

How the data were processed

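UWB1.289 is a human ovarian cancer cell line that carries a damaging BRCA1 mutation in exon 11 and has lost the other allele. It was compared with its isogenic partner, in which wild-type BRCA1 was put back by forced expression. Acetylation of lysine 27 on histone H3 (H3K27ac), a mark of active promoters and enhancers, was profiled by chromatin immunoprecipitation and sequencing in 2 libraries per genotype. The 4 input libraries were not analysed here. Per the submitters' processing notes, Bowtie and Bowtie2, MACS2 and the GRCh38 (hg38) build were used; versions and settings are not given in the sources used here.

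Each of the 4 H3K27ac libraries came with 1 list of regions. The value given for each region is a score made by the authors, and no header or label says how it was computed. The region names number the libraries and the conditions in the manner of a pairwise MACS2 comparison, every region was at least 200 bp wide, and every score lay above 3. From this layout the lists were read as regions higher in that library than in the library of the other genotype with the same number. This reading is inferred from the names and values, not stated by the labels. Pair 1 is mutant library 1 with restored library 1, and pair 2 is mutant library 2 with restored library 2. Regions that do not differ are not listed, so a missing region says nothing about whether the mark was present. In the deposited lists each region also carries a transcript, a gene symbol, the distance from its midpoint to the transcription start site (TSS) and a location class, all of them the authors'. The score was used to rank or filter regions within a list. It also served to rank genes by the smaller of their 2 scores, which come from different lists, and to match random lists.

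The plan written before the data were examined assumed peaks called per library against input. With lists of differences, a region called in both mutant and neither restored library means a region listed as higher in mutant in both pairs. Lists of the same pair cannot overlap by construction, so overlap between mutant library 1 and restored library 2, or mutant library 2 and restored library 1, served as the check on opposite directions. Regions called in all 4 libraries do not exist in such lists, so the planned distal comparison was run between regions higher in mutant and regions higher in restored cells. The planned motif comparison was not run, because no genome sequence was used here.

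Regions on chromosomes 1 to 22 and X were kept, which left out 7 of 56406. Overlapping or touching regions of the 4 lists were merged, and a library lists a merged region if any of its regions overlaps it by at least 1 bp. Jaccard indices of covered bases were computed with bedtools 2.31.1. Gene symbols were matched to RefSeq protein-coding genes (GRCh38.p14), 8142 by symbol and 522 by an older name out of 15345 symbols in the lists. As a check on the build, 96.6% of 12302 TSS positions implied by the authors' distances lay within 1 kb of the matched gene. A gene was called in a list if a region overlapped the window of 1 kb on either side of any TSS implied by the lists or of the outermost 5' end in RefSeq. The reference table gives no strand, so strand came from the lists, and 1300 genes of unknown strand with a region at either end were left out. This left 18674 of 19974 genes. The lists gave a strand for 8658 genes. Genes of unknown strand without a region at either end were kept and counted as not listed. A gene called in both pairs need not have the same region in both. At CSF2, PSME1, RPL3, RPS26, STING1, ULBP1 and ULBP3, among others, each mutant library listed 1 region and these did not overlap. A window can hold the promoter of a neighbouring gene, and where the authors assigned a region to another gene this is said for several of the named genes; of 108 named genes, 80 kept their class when only regions assigned to them within 1 kb counted.

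The 20 gene lists, with 775 genes in all, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule named BRCA1 first. From each list it took up to 4 genes higher in mutant and up to 2 higher in restored cells in both pairs, ranked by the smaller of the 2 scores. It added the 10 highest ranked genes of each direction, and STING1, CGAS, CCL5, CXCL10 and VEGFA whatever their class. Some genes that this rule selects are not reported here. Numbers of regions and Jaccard indices were compared by exact permutation tests. With 2 libraries against 2 these cannot give a p below 0.333, or below 0.5 if the lists are kept in pairs. Lists were tested with Fisher's exact test (two-sided) and Benjamini-Hochberg adjustment over the 20 lists, at 0.05. The main background was the 2337 protein-coding genes listed in both libraries of at least 1 genotype. These are called genes listed in both pairs. They leave out genes given opposite directions by the pairs, 141 by mutant 1 and restored 2 and 3 by mutant 2 and restored 1. Leaving these out raised the mutant share with which each list was compared. Genes and regions are not replicates, so these tests describe the 4 libraries. No label says that the libraries came from separate cultures, so their spread may be technical.

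The region and list steps were tested on simulated data. With 2337 genes, a planted list of 25 genes that were all higher in mutant was called in 7% of 200 simulations, because most listed genes already lean that way. A list with the background share was called in 0 of 200. A planted list of 25 genes with 50% of them higher in restored cells was called in 84.5%. Smaller lists were not simulated, so this power does not carry over to them. The list test therefore had little power toward mutant, and less for lists of fewer genes. Failing it in that direction does not show that a list is like other genes. Sequencing depth per library is unknown, since the lists hold no read counts. Intervals on shares are 95% exact (Clopper-Pearson) intervals and cover counting error only.

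Alternatives were the upper part of each list by score, equal numbers of regions, leaving out each library, a replicate block, stricter overlap, merging within 1 kb, all sequences, a 2.5 kb window, the outermost 5' end alone, all classified protein-coding genes as background, and random lists matched on score. Added after seeing the data were each pair alone, the authors' gene assignment within 1 kb or at any distance, genes of unknown strand kept, and chromosome 5 left out. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.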

Results

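H3K27ac was compared between UWB1.289 cells, which carry a damaging BRCA1 mutation, and the isogenic line with wild-type BRCA1 restored. BRCA1 is a DNA repair protein that acts in homologous recombination. The series title ties loss of BRCA1 to DNA sensing and immune recognition, so genes of these programs were among the lists examined. Each genotype had 2 libraries, called mutant 1 and 2 and restored 1 and 2. Each list was read as the regions with more H3K27ac than in the library of the same number from the other genotype. Coordinates are GRCh38, and scores are the authors' own. No input library was analysed here.

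Far more regions were listed as higher in BRCA1-mutant cells than in restored cells. Mutant 1 listed 23802 regions and mutant 2 listed 19199, against 5451 in restored 1 and 7954 in restored 2. The means were 21500.5 ± 3254.81 and 6702.5 ± 1769.89 regions (SD, n = 2 each), a ratio of 3.21. The ratio was 4.37 in pair 1 and 2.41 in pair 2. The exact permutation test (two-sided) gave p = 0.333, the smallest value that 2 against 2 libraries allow. That test treats the 4 lists as independent; with the lists kept paired, an exact permutation test within pairs, chosen after seeing the data, gave p = 0.5, also the smallest possible. The listed regions covered 10.7 and 8.12 Mb in mutant and 2.07 and 3.31 Mb in restored libraries, with median widths of 341, 320, 288 and 318 bp. By the authors' location, introns held 45.1% and 43.5% of the mutant regions and 39.9% and 45.7% of the restored regions.

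**Figure D1:**
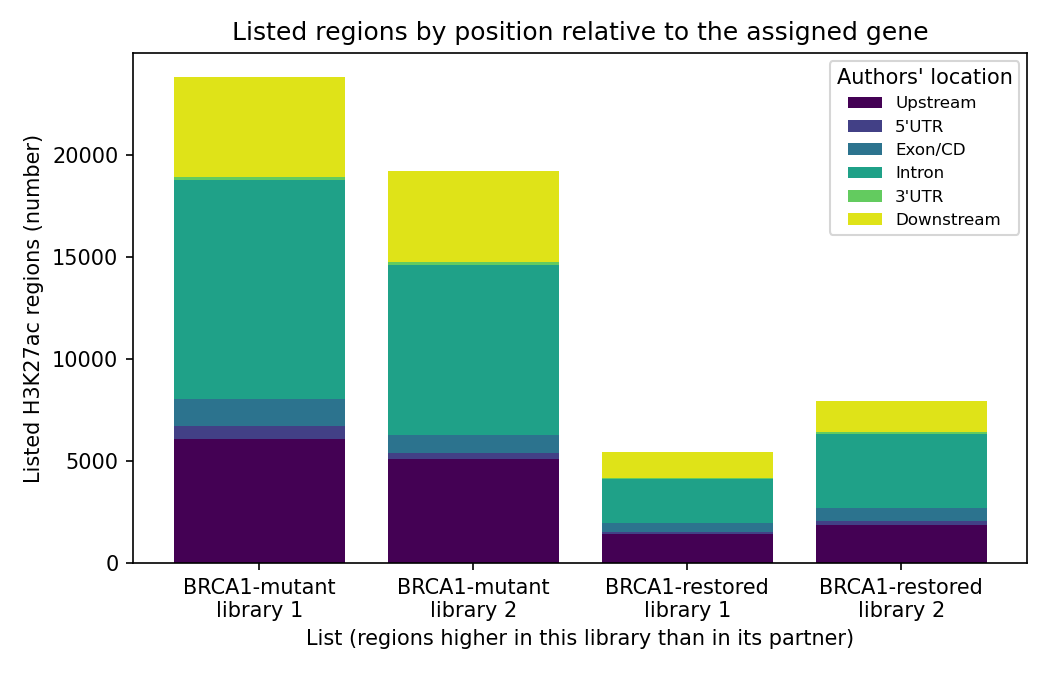
Number of listed H3K27ac regions (vertical axis) in each of the 4 lists (horizontal axis), stacked by the authors' location relative to the assigned gene. The mutant bars reach 23802 and 19199 regions and the restored bars 5451 and 7954; each bar is 1 library, with no error bar.

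At BRCA1 itself, the TSS that the authors' annotation uses had 1 listed region. It was higher in mutant 1 (chromosome 17, 43124633 to 43125263, intronic, score 5.82), and no other library listed that TSS. The RefSeq span of BRCA1 ends at 43170327, beside the promoter of NBR1, and there mutant 1 (43171179 to 43171466, score 8.65) and mutant 2 (43170835 to 43171072, score 5.97) both listed regions. The authors assigned these regions to NBR1, so the call of BRCA1 as higher in mutant in both pairs rests on its neighbour's promoter. Restored 2 listed 2 regions near the 3' end of BRCA1, at 43045591 to 43045879 (exonic, score 16.4) and 43046378 to 43046632 (intronic, score 19.2), 79.6 and 78.9 kb downstream of the TSS. The listed regions show H3K27ac differences and do not measure BRCA1 restoration, so they do not check the labels.

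The pairs gave nearly the same direction wherever both listed a region. After merging, 41897 regions remained, of which 10452 were higher in mutant in both pairs and 1978 were higher in restored cells in both pairs, a ratio of 5.28. Of 12447 regions listed in both pairs, 12430 had the same direction (99.9%, 95% exact interval 99.8 to 99.9%). Regions shared between mutant 1 and restored 2 numbered 17, and mutant 2 shared 0 with restored 1. Another 29450 merged regions were listed in 1 pair alone. The Jaccard index was 0.309 between the mutant libraries and 0.174 between the restored libraries, and at most 0.000146 between genotypes (exact permutation test p = 0.333, the smallest possible). Zero overlap within a pair is fixed by construction, so this permutation test carries little weight. When each library was cut to its 5451 strongest regions, 1670 regions were higher in mutant and 1647 in restored cells in both pairs, and equal list lengths limit how far these counts can differ.

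Among gene promoters, 1844 genes had a TSS listed as higher in mutant in both pairs and 368 had one listed as higher in restored cells in both pairs, a ratio of 5.01. Another 125 genes were listed in both libraries of 1 genotype and also in the other genotype. Opposite directions in the pairs were given to 141 genes by mutant 1 and restored 2 and to 3 genes by mutant 2 and restored 1. The strongest genes higher in mutant were EVC, a ciliary protein gene (scores 47.7 and 48.4), LIN28B, an RNA-binding repressor of let-7 microRNAs (42.5 and 39.5), PDZK1IP1 (35.8 and 37.9), VEPH1 (33.1 and 38.6) and CD40, a TNF receptor family member of immune signalling (32.3 and 30.3). ROBO4, HCAR1, EFNB1, EHF and CHST11 completed these 10. The strongest genes higher in restored cells included FGD3 (45.4 and 50.9), DNAJC6 (36.0 and 52.0), CERS4, a ceramide synthase gene (27.6 and 33.8), and PASD1 (28.2 and 26.8). DISC1, POLRMT, SORCS2, PTF1A and KLHL33 were also among them. The EVC regions lay at 5752939 to 5753853 and 5752917 to 5754775 on chromosome 4, intronic and exonic. The FGD3 regions lay at 92974678 to 92975799 and 92974419 to 92975869 on chromosome 9, exonic and intronic. With the 5451 strongest regions per library, 235 genes were higher in mutant and 329 in restored cells, a ratio in the other direction. Without mutant 2 the mutant count was 3913, and without restored 1 or restored 2 the restored count was 1162 or 553, because a single library then decides the class.

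TSS windows of interferon-stimulated genes were listed in the mutant direction wherever both pairs listed them. Of 57 classified genes of this list, 25 were higher in mutant in both pairs and 0 in restored cells. These included IFITM1, which blocks viral entry (scores 20.8 and 22.3), TRIM25, a ubiquitin ligase of the RIG-I pathway (22.4 and 14.2), OAS2, a sensor of double-stranded RNA (34.5 and 12.04), and SP100 (11.1 and 16.8). OAS1 (9.63 and 9.21), OAS3 (9.40 and 8.70), IRF9, BST2, PARP9, DTX3L, DDX60 and IFITM3 were among the others. The TRIM25 regions were assigned by the authors to a neighbouring transcript, and BST2, PARP9 and DTX3L had regions assigned to them in 1 mutant library only. By the authors' assignment at any distance, GBP1 had 1 and 2 regions and UBE2L6 had 1 and 4 regions in the restored libraries, and 0 in the mutant libraries. Another 10, MX1, MX2, IFI27 and USP18 among them, were listed in 1 mutant library, and the TSS of UBE2L6 and CMPK2 in 1 restored library. Among the 2337 genes listed in both libraries of at least 1 genotype, 25 of 25 were higher in mutant (95% exact interval 86.3 to 100%) against 78.7% of the other genes. This did not pass Fisher's exact test after adjustment (p = 0.00495, adjusted p = 0.0989). The 25 genes fell in 18 loci. Neighbours such as OAS1, OAS2 and OAS3 count separately, and 1 region can count for more than 1 gene. The interval and p treat the genes as independent. The background also leaves out genes with opposite directions in the pairs, which raised the 78.7%. Adjusted p ranged from 5.38e-10 to 1 over the alternatives of this Fisher's exact test. With 1 pair alone or a library left out, a single list decides a class. The interferon list did not pass under most alternatives. Among these were equal numbers (0.464), the outermost 5' end alone (0.449) and the authors' assignment within 1 kb (0.238). It passed with a 2.5 kb window (0.0190), against all classified protein-coding genes (5.38e-10), in pair 2 alone (0.00224), and without restored 1 (0.00106) or restored 2 (0.0174).

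**Figure D2:**
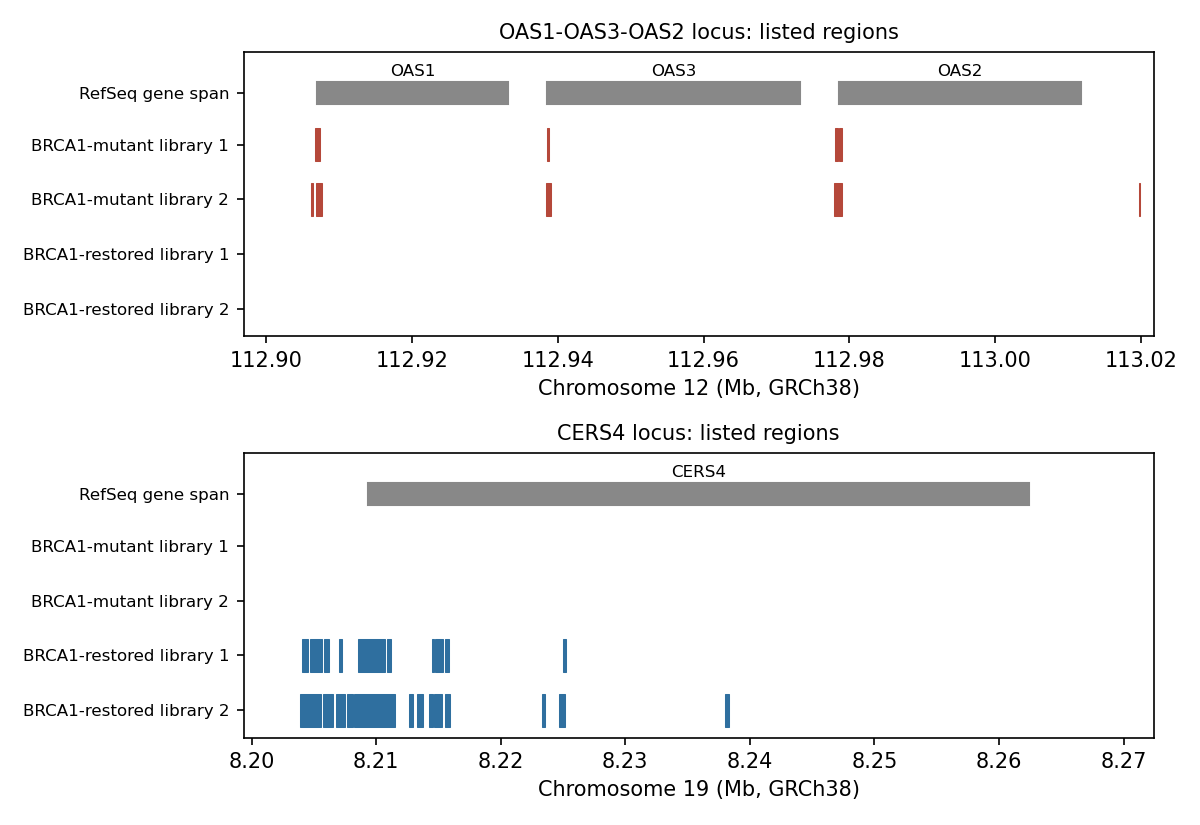
Position in Mb (horizontal axis) of listed regions in each library (rows) across the OAS1, OAS3 and OAS2 genes on chromosome 12 and across CERS4 on chromosome 19, with RefSeq gene spans in grey. The mutant libraries listed 4 and 5 regions in the first window and the restored libraries 10 and 13 in the second, with 0 in the opposite genotype.

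Of 31 classified genes of innate sensing, a list that also holds TLR4 and TICAM1, 8 were higher in mutant in both pairs and 0 in restored cells. STING1, the adaptor downstream of cGAS, was one of them, with 1 region upstream in mutant 1 (chromosome 5, 139483085 to 139483300, score 6.90) and 1 intronic region in mutant 2 (139481866 to 139482209, score 5.32). These STING1 regions do not overlap, and the call was lost in the upper part of each list and at equal numbers. DHX58 (13.7 and 13.9), TRIM56 (10.9 and 9.70), IFIH1, the RNA sensor MDA5 (11.1 and 9.43), and HMGB1 (9.60 and 8.29) also qualified, although the authors assigned the mutant 2 region at IFIH1 to GCA and the mutant 1 region at HMGB1 to USPL1. These calls were kept in the upper part of each list. At equal numbers that of DHX58 was kept and those of TRIM56, IFIH1 and HMGB1 were lost. Another 7 were listed in 1 mutant library, and DDX41 and RNASEH2A in 1 restored library. Of the 7, CGAS, the cytosolic DNA sensor, was listed in mutant 1 alone (chromosome 6, 73451003 to 73451414, intronic, score 6.28). The list did not pass Fisher's exact test (100% against 78.8% of other listed genes, adjusted p = 0.893).

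Chemokine and cytokine genes gave 12 of 44 higher in mutant and 0 in restored cells in both pairs. LIF (15.4 and 17.1), IL1A (22.4 and 14.5), CSF2 (13.9 and 10.95) and CX3CL1 (24.0 and 8.08) led, with IL6, TNF, CSF1 and CXCL16 among the rest. The LIF regions were assigned by the authors to an overlapping transcript. CCL5 and CXCL10, chemokines that recruit T cells, had no listed TSS in any library. NF-kB targets gave 12 of 30 and 0 of 30, with NFKBIE (21.6 and 16.3), TNIP1 (16.9 and 15.6), TRAF2 (16.3 and 14.4) and TNFAIP3 (18.95 and 9.42). Neither list passed Fisher's exact test among genes listed in both pairs (12 of 12, adjusted p = 0.825; 12 of 14, adjusted p = 0.938).

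Antigen presentation and ligands of immune cells had genes listed in both directions. Of 20 class I genes, TAPBPL (12.8 and 6.40) and PSME1 (12.6 and 4.21) were higher in mutant and CANX (5.44 and 5.95, regions assigned to CBY3) in restored cells. Of 15 class II genes, CTSS (15.9 and 17.9) was higher in mutant. Of 29 immune ligand genes, CD40 and the genes of the NK cell ligands ULBP1 (20.3 and 8.43) and ULBP3 (7.84 and 5.62) were higher in mutant. VTCN1, the checkpoint ligand B7-H4 (16.3 and 6.72), and MICA, another ligand of NK cells (5.83 and 6.58), were higher in restored cells. The strongest VTCN1 regions lay apart, at 117172787 to 117173082 in restored 1 and 117210033 to 117210233 in restored 2. The calls of TAPBPL, PSME1 and ULBP3 were lost in the upper part of each list and at equal numbers. Those of CANX, VTCN1 and MICA were lost in the upper part, and that of ULBP1 at equal numbers. Adjusted p from Fisher's exact test was 0.893, 1 and 0.893 for the 3 lists in the mutant direction.

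Lineage genes went in either direction at single promoters. Of 50 mesenchymal genes 18 were higher in mutant, including the transcription factor gene TWIST2 (28.1 and 54.3), COL6A2 (23.3 and 30.9) and ITGA5 (20.4 and 29.4). CNN1, a smooth muscle calponin gene (14.4 and 33.4), and ITGB3 (6.21 and 14.9) were higher in restored cells. Of 41 epithelial genes, 14 were higher in mutant and 0 in restored cells, with EHF (29.1 and 40.2), LAMB3 (21.7 and 11.7), EPCAM (22.8 and 10.95) and KRT7 (10.7 and 7.65). Of 31 Müllerian and serous ovarian genes, LHX1 (22.7 and 20.7), MUC1 (14.7 and 15.9), MECOM (24.998 and 13.1), CLDN16 and SLPI were higher in mutant. ESR1, the estrogen receptor (5.25 and 22.6), and TFAP2A (5.57 and 5.21) were higher in restored cells. HOX genes gave 5 of 38 in mutant, including HOXB2 (12.9 and 15.1) and HOXB7 (10.5 and 7.20), and 0 in restored cells. Of 39 blood and endothelial genes, fixed as markers of other cells, CDH5 (21.3 and 16.4) and ROBO4 (29.9 and 45.2) were higher in mutant and ESAM (7.59 and 11.1) in restored cells. Adjusted p from Fisher's exact test in the mutant direction was 0.893 for the mesenchymal and epithelial lists, 0.938 for the Müllerian list, 1 for HOX and 0.893 for the other lineages.

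Of 43 homologous recombination genes, RAD51B (17.7 and 13.3), RMI1 (7.74 and 4.69), BLM (4.65 and 4.89) and FANCF were higher in mutant, and BRCA1 was so only through the promoter of NBR1. The strongest RAD51B regions, at 68472425 to 68473538 in mutant 1 and 68546128 to 68547566 in mutant 2 on chromosome 14, were intronic and lay at different internal TSS, and the call was lost at the outermost 5' end. UIMC1, which recruits BRCA1 to damage sites (3.88 and 5.87), was higher in restored cells. The regions at RMI1, BLM and UIMC1 were assigned by the authors to HNRNPK, CRTC3-AS1 and ZNF346. Of 40 other repair genes, 6 were higher in mutant and 0 in restored cells, with PARG (13.8 and 12.1), which removes poly(ADP-ribose), PARP1, which adds it (15.6 and 9.44), PARP3 (9.25 and 4.749) and DDB2 (8.56 and 4.41). Neither repair list passed Fisher's exact test (adjusted p = 1 and 0.893).

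Of 45 cell cycle genes, 9 were higher in mutant, with CCND2 (7.90 and 8.59), CDK6 (8.18 and 6.78), AURKB (6.58 and 7.91) and CDK2 (19.9 and 5.78). E2F2 (5.48 and 7.40) and E2F1 (3.72 and 6.92) were higher in restored cells. Of 26 p53 targets, GADD45A (6.92 and 7.53) and DDB2 were higher in mutant and PHLDA3 (7.70 and 20.4) in restored cells. Of 32 AP-1 and immediate early genes, 8 were higher in mutant, with KLF6 (9.86 and 9.76), KLF10 (8.42 and 9.85), MYC (8.18 and 15.3) and MAFF (17.8 and 7.53). EGR1 (12.8 and 6.85) and DUSP1 (5.196 and 12.96) were higher in restored cells, although the DUSP1 regions were assigned to another transcript and its call was lost with a 2.5 kb window. Both lie on the long arm of chromosome 5, as do CANX and UIMC1. Of 38 angiogenesis genes, 11 were higher in mutant, with EDN1 (17.3 and 13.4), CCN2 (33.8 and 9.77) and FGF2 (18.2 and 8.39). FLT1, the receptor VEGFR1 (21.9 and 18.4), EPAS1 (8.33 and 7.07), TIMP3 and SEMA3F were higher in restored cells. VEGFA had a TSS region in mutant 1 alone (score 6.89), while downstream of its TSS mutant 1 listed a region at 21.1 kb (6.60) and mutant 2 listed regions at 20.3 kb (12.7) and 21.1 kb (4.22). Fisher's exact test in the mutant direction gave adjusted p = 0.938, 0.893, 1 and 0.893 for these 4 lists.

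Promoters that are active in most cells also leaned toward mutant. Of 68 ribosomal protein genes, 13 were higher in mutant, including RPL3 (11.1 and 9.36) and RPS26 (5.64 and 6.12), and RPL10A (3.77 and 5.68) was higher in restored cells. Of 33 ubiquitously expressed genes, 7 were higher in mutant and 0 in restored cells, with SDHA (21.9 and 8.05), ACTB (14.5 and 6.74) and YWHAZ (12.02 and 5.05). Adjusted p from Fisher's exact test was 0.938 and 0.893.

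Calls of some named genes depended on how regions were tied to genes, and others on the scores of their regions. When only regions the authors assigned to the gene within 1 kb counted, a setting chosen after seeing the data, the calls of BRCA1, TRIM25, IFIH1, HMGB1, LIF, TAPBPL, CANX, CTSS, NFKBIE, TNIP1, RMI1, BLM, UIMC1, PARG, CCND2, CDK6, KLF10, DUSP1, CCN2, FGF2, LAMB3, LHX1, MECOM, HOXB2, HOXB7 and ESAM were lost. With the outermost 5' end alone, those of LIN28B, VEPH1, FGD3, DNAJC6, DISC1, POLRMT, VTCN1, MICA, RAD51B, PARG, CDK6, CDK2, MAFF, EDN1, CNN1, MECOM, CLDN16, ESR1, TFAP2A and RPL3 were lost. In the upper part of each list, restored calls of UIMC1, E2F1, E2F2, EGR1, DUSP1, ITGB3, ESR1, TFAP2A and RPL10A were also lost. So were mutant calls of RMI1, BLM, PARP3, DDB2, CDK6, AURKB, CDK2, GADD45A, CLDN16, RPS26, ACTB and YWHAZ, among others. Equal numbers removed further calls, among them SP100, CX3CL1, CCND2, KLF6, KLF10, MYC, MAFF, FGF2, KRT7, HOXB7, RPL3 and SDHA.

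**Figure D3:**
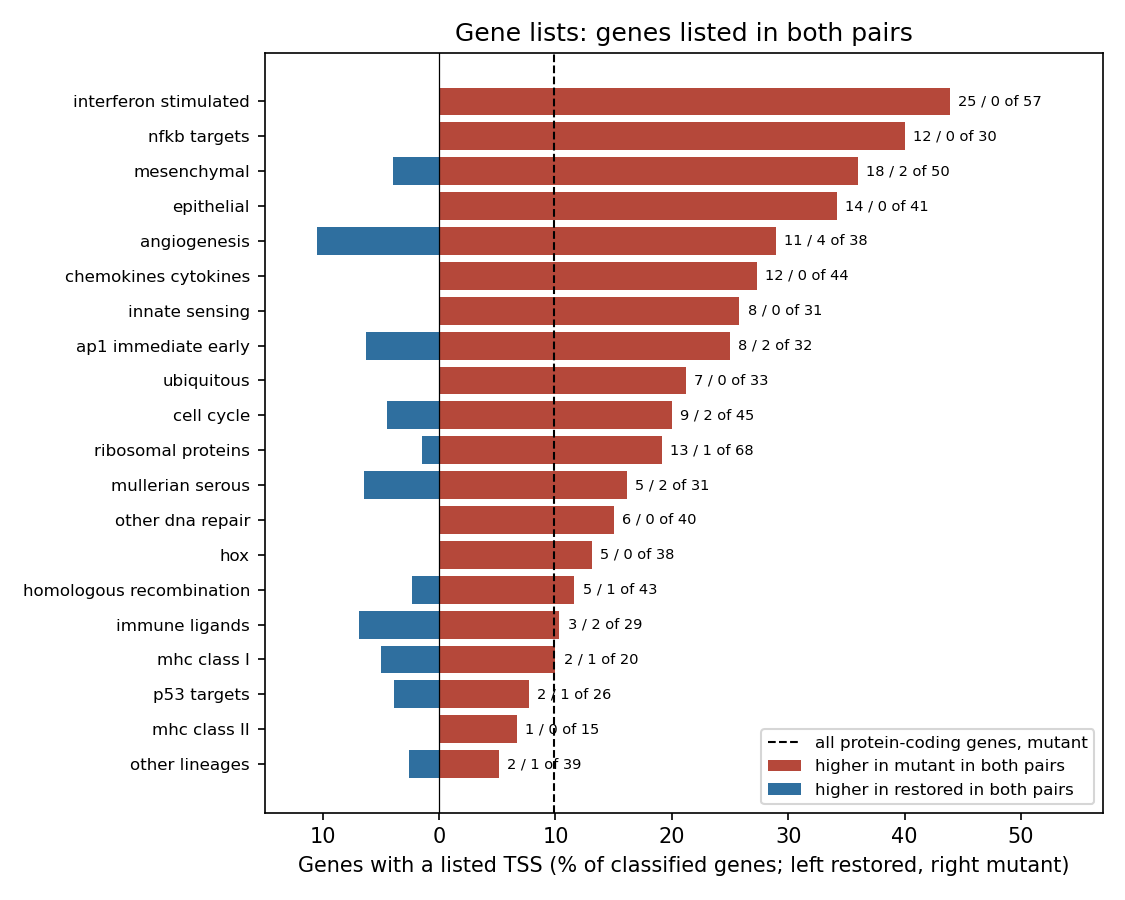
Share of classified genes of each list (rows) with a TSS listed in both pairs as higher in mutant (right) or in restored cells (left), in percent, with the counts as mutant / restored of classified. The dashed line marks the 9.87% of the 18674 classified protein-coding genes that were higher in mutant. Interferon-stimulated genes reached 43.9%.

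Across the 20 lists, 0 passed adjusted Fisher's exact tests in the mutant direction and 0 in the restored direction, when compared with other genes of the main background of 2337. Toward mutant, this result was close to fixed in advance. The interferon list, the largest there, reached its maximum of 25 of 25 and did not pass. The other lists held 20 genes or fewer there, so a full share in any 1 of them alone could not pass. Toward restored, power was simulated for 25 genes only and is unknown for these smaller lists. For immune ligands, 2 of 5 genes higher in restored cells gave an unadjusted Fisher's exact p = 0.179. At an unadjusted p under 0.05, interferon-stimulated genes passed in the mutant direction (p = 0.00495) and also in the restored direction, as a lower share (0 of 25 against 15.9%, Fisher's exact p = 0.0240, adjusted p = 0.480). In the restored direction, a lower share passed for interferon-stimulated genes in pair 2 alone (Fisher's exact test, adjusted p = 0.00493), and for the interferon and NF-kB lists without restored 1 (adjusted p = 0.0194 for both). Random lists matched on score passed for 0 lists. Against all 18674 classified genes, 9 lists had more genes higher in mutant, namely the interferon (25 of 57), NF-kB (12 of 30), mesenchymal (18 of 50), epithelial (14 of 41), angiogenesis (11 of 38), chemokine (12 of 44), innate sensing (8 of 31), AP-1 (8 of 32) and ribosomal (13 of 68) lists. Adjusted p from Fisher's exact test ranged from 5.38e-10 for the interferon list to 0.0483 for the ribosomal list, and 9.87% of all these genes were higher in mutant. In that comparison 0 lists had more genes higher in restored cells. Genes of unknown strand stayed in that background only where they had no region at either end. They could not count as higher in either genotype, so this comparison was partly fixed by the lists themselves.

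Most differential regions lay outside the TSS windows used, in both directions. These windows left out genes of unknown strand, so regions at the promoters of such genes counted as outside and raised the shares below. Of the 10452 regions higher in mutant, 80.4% overlapped no TSS window, against 79.3% of the 1978 higher in restored cells, a difference of 1.09 points (Fisher's exact test p = 0.268). It was 2.76 points with a 2.5 kb window (Fisher's exact p = 0.0101) and 6.50 points with equal numbers of regions (Fisher's exact p = 4.52e-07), both past 0.05. Its direction depended on single libraries. It was -5.03 points without mutant 2 (Fisher's exact p = 5.52e-07) and -5.57 without restored 2 (p = 8.65e-19), but 2.69 without mutant 1 (p = 0.00370) and 2.76 without restored 1 (p = 5.44e-06).

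More regions were higher in mutant on 23 of 23 chromosomes in pair 1 and on 21 of 23 in pair 2, where chromosomes 5 and 19 had more regions higher in restored cells. On chromosome 5, restored regions made up 36.5% of listed regions in pair 1 and 56.99% in pair 2, against 18.6% and 29.3% over all chromosomes. On chromosome 19 they made up 32.4% and 53.3%. Chromosome 5 held 7.56% and 8.86% of the restored regions and 3.01% and 2.77% of the mutant regions. The long arm carried this difference: restored regions made up 57.4% of its listed regions (44.0% and 68.5% in the pairs), against 19.6% on the short arm and 22.7% on all other chromosomes. The long arm held 56 of the 368 genes higher in restored cells (15.2%) and 13 of the 1844 higher in mutant (0.705%), STING1, CSF2 and TNIP1 among the latter. No test across libraries was planned for chromosome shares. The split into arms at 50 Mb was chosen after the values were seen.

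**Figure D4:**
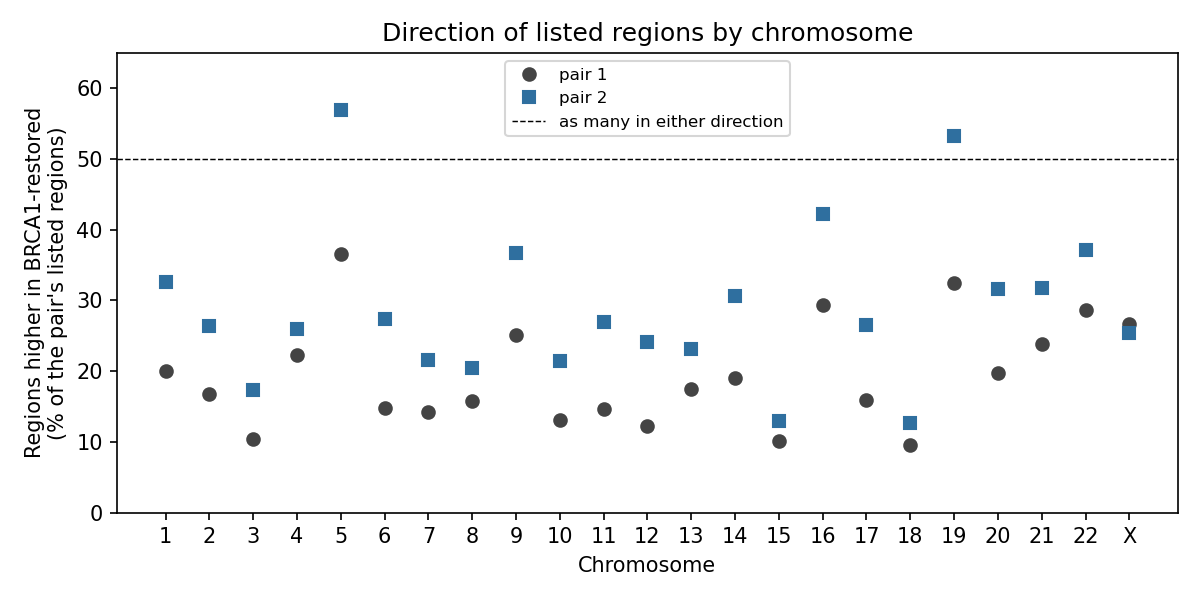
Share of listed regions that were higher in BRCA1-restored cells (vertical axis, percent of the listed regions of each pair) for chromosomes 1 to 22 and X (horizontal axis), with pair 1 as circles and pair 2 as squares. Chromosome 5 reached 36.5% and 56.99% and chromosome 19 reached 32.4% and 53.3%.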

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

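Of the alternatives, each pair alone, the permutation within pairs, the authors' gene assignment, genes of unknown strand and leaving out chromosome 5 were chosen after the results were seen. The correlation of replicate differences between the genotypes was 0.0212. Regions were almost never listed in both genotypes, so this value is small by construction and cannot show whether a block by library number was present. The replicate block gave 10452 and 1978 regions and 1844 and 368 genes, as it must by construction. Regions higher in mutant and in restored cells in both pairs numbered 4301 and 823 in the upper part of each list by score, and 1670 and 1647 at equal numbers. They numbered 23802 and 5451 in pair 1 alone, and 19199 and 7954 in pair 2 alone. Genes numbered 623 and 129 in the upper part, 235 and 329 at equal numbers, 4103 and 563 in pair 1, and 2348 and 1343 in pair 2. Without chromosome 5 there were 10198 and 1805 regions and 1811 and 310 genes. At any distance by the authors' assignment, 2683 and 606 genes qualified. Shorter lists and the need for 1 pair only change these counts by construction. Leaving out 1 library at a time gave 10452 to 23785 and 1978 to 7937 regions, and 1859 to 3913 and 375 to 1162 genes. The ratio of listed regions was then 2.70 to 3.94 and the chromosome 5 ratio of restored to mutant share 2.62 to 3.07, against 2.84 with all libraries. The number of lists with more genes higher in mutant was 9 against all classified protein-coding genes, 1 with a 2.5 kb window, 1 in pair 2 alone, 1 at any distance (chemokines and cytokines), 0 to 1 when a library was left out, and 0 under the other settings. The number with more genes higher in restored cells was 0 in every setting run. The difference in distal share was 2.76 points with a 2.5 kb window (Fisher's exact p = 0.0101), 6.50 at equal numbers (Fisher's exact p = 4.52e-07), and -5.57 to 2.76 without a library; the cause was not tested. Of 108 named genes, 80 kept their class when only regions the authors assigned within 1 kb counted, 87 with the outermost 5' end alone, 76 in the upper part of each list and 70 at equal numbers, and 0 changed direction under any setting. Most named genes were chosen for being listed in 1 genotype only. Settings that only take away regions, libraries or TSS cannot reverse such a call, so the 0 carries little weight. Motif comparisons were not run. Depth was unknown and cannot be separated from the number of regions listed.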

Other observations

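Apart from the planned Fisher's exact test of the interferon list, the tests below were chosen after the results were seen. Some genes carried long runs of listed regions by the authors' assignment. In the mutant direction, RAD51B had 60 and 57 regions over 237 kb of chromosome 14, TGM2, a transglutaminase gene, 35 and 32, WNT7A 29 and 40, ITGB6, an epithelial integrin gene, 25 and 31, and SMAD3, a mediator of TGF-beta signalling, 24 and 26. The restored libraries listed 1 and 2 regions at RAD51B, 0 and 1 at WNT7A and ITGB6, and 0 and 0 at TGM2 and SMAD3. In the restored direction, ERGIC1 and KCNIP3 each had 16 and 21 regions, SORCS2 14 and 16, CD9, a tetraspanin gene, 11 and 15, and KAZN 10 and 37. The mutant libraries listed 3 and 1 regions at ERGIC1, 1 and 2 at CD9, 1 and 3 at KAZN, and 0 and 0 at KCNIP3 and SORCS2. ERGIC1 lies on the long arm of chromosome 5. These genes were singled out by their number of regions.

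Some restored regions clustered in 1 library more than in the other. In the 5 Mb bin at 85 to 90 Mb of chromosome 8, restored 1 listed 58 regions and restored 2 listed 18, and at 115 to 120 Mb of chromosome X they listed 50 and 11. In the first 5 Mb of chromosome 1 they listed 116 and 91, against 53 and 29 in the mutant libraries. CD274, the checkpoint ligand PD-L1, had 1 assigned region, 3.08 kb upstream in mutant 2 (score 10.1). Over the 23 chromosomes, gene density and the restored share gave Pearson's r = 0.349 in pair 1 (permutation p = 0.0984) and 0.513 in pair 2 (permutation p = 0.0203, adjusted p = 0.0407), and Spearman's rho 0.147 (permutation p = 0.501) and 0.457 (permutation p = 0.0298, adjusted p = 0.0595). Without chromosomes 17 and 19, r was 0.175 and 0.332.

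The excess of regions higher in BRCA1-mutant cells was spread over the genome. In 90.7% of 503 bins of 5 Mb mutant regions outnumbered restored regions, which argues against a few chromosome segments of altered copy number as the whole cause. A difference in scaling, depth or immunoprecipitation efficiency between the libraries stays open. Promoters of ubiquitous and ribosomal genes leaned to mutant in 90.9% of 22 listed cases (95% exact interval 70.8 to 98.9%), no less than the 78.8% of other listed genes, which is consistent with such a difference. A gain of H3K27ac with loss of BRCA1 was not tested apart from it.

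Whether the promoters of interferon-stimulated genes stand apart from the general excess is undecided. The 25 genes higher in mutant in both pairs fell in 18 loci on 14 chromosomes, against copy number of 1 locus. A list that merely holds more active promoters stays open: the share of 43.9% was above the 19.8% of 101 ubiquitous and ribosomal genes (Fisher's exact p = 0.00178) but not clearly above the 35.2% of 91 epithelial and mesenchymal genes (Fisher's exact p = 0.303), groups compared after their shares had been seen. The general excess toward mutant also stays open, because 25 of 25 against 78.7% gave an adjusted p of 0.0989 in a Fisher's exact test with little power. The background of that test left out genes with opposite directions in the pairs, which raised the 78.7%. An effect of BRCA1 loss on this program is a hypothesis that these lists leave open.

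The restored share on chromosome 5 has no decided cause. Its 2 arms differed by 24.5 points in pair 1 and 48.7 in pair 2, against at most 25.3 and 38.0 on the others of 21 chromosomes with at least 20 regions on each side of the same split. The short arm lay above the other chromosomes in pair 1 (19.5% against 17.9%) and below in pair 2 (19.8% against 28.0%). Copy number of the whole chromosome would raise both arms. Both values of pair 2 argue against it, but those of pair 1 do not, so it was not excluded. Chromosome 5 ranks 19 of 23 by gene density, which argues against gene density. On the long arm, 88.5% of 26 bins lay above the median bin of the genome, but this restates the share of an arm chosen from the same regions and lends no support to copy number of that arm. Copy number and a regulatory difference along the arm cannot be told apart here, and the input libraries were not analysed here.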
